A study of Mus musculus with 19 samples.

How the data were processed

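RNA was measured by droplet single-nucleus sequencing (10x Chromium 3' version 3 chemistry, per the labels) in nuclei of mouse hippocampus, in 19 libraries of 5 groups. The deposited matrices hold raw UMI counts per gene and barcode for 31053 genes. Per the file headers and the authors' processing notes they were made with Cell Ranger 3.1.0, and the notes name the mm10 genome and Seurat 3.0. The deposited barcode and feature files hold no measurement but the cell barcodes and the gene identifiers with symbols. The annotation release and whether intronic reads were counted are not given. The matrices are the filtered ones, with 8835 to 13139 barcodes and 35942608 to 52214368 UMIs per library. Gene positions come from the GENCODE vM21 annotation of mm10, in which 30934 of the 31053 identifiers were found.

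Nuclei with 300 to 8000 genes and at most 5% mitochondrial UMIs were kept. Doublet scores were computed per library with Scrublet in scanpy 1.11.5, and the highest scores were removed at 0.8% of the barcodes per 1000 barcodes, 20147 in all. Of 218320 barcodes 197074 nuclei were kept. Counts were scaled to 10000 per nucleus and log-transformed. The 2000 most variable genes, without mitochondrial genes and 9 genes named in the comparisons or linked to sex, gave 30 principal components. A graph of 15 neighbours was clustered with the Leiden method at resolution 1.0 (igraph implementation, called from scanpy). A cluster was named when at least 3 listed markers of a class were above 20 CPM and more than 1 higher on the log2 scale than over the other clusters (pseudocount 20 CPM), with at least 2 times the markers of any other class. Clusters that fell short or held markers of more than 1 class were left unnamed and not tested. So were clusters whose 10 top genes pointed to another class, or whose UMI count was over 5 times that of the class's largest cluster.

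UMIs were summed per library and class. The 6 classes with at least 20 nuclei in every library and a comparison of interest were tested, each with edgeR 4.0.16 quasi-likelihood fits over all 5 groups, TMM normalization and filterByExpr, and genes were called at a Benjamini-Hochberg adjusted p of 0.05 over the genes tested in that class and contrast. A log2 fold change is the fitted one with its SE, and CPM values are per summed library without normalization factors. The contrasts were P301S within R47H, MK-2206 within P301S, MK-2206 without P301S, R47H against mTrem2 and, in microglia, the interaction of MK-2206 and P301S. A named gene is 1 of the 8 (microglia) or 4 (other classes) largest or smallest log2 fold changes among called genes above the median level, or 1 of up to 4 called members of a list with the smallest p. With fewer than 5 genes called, all of them were named. In microglia, the 2 members of each list with the smallest p were then given as values. Trem2, Mapt, Prnp, Xist, Akt1 and Akt2 were always read, and predicted genes were skipped. Some single-gene results are not reported here.

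Gene lists were homeostatic microglia, disease-associated microglia, NF-kB and cytokine, interferon response, antigen presentation, PI3K-AKT pathway components, FOXO targets, glycolysis, sterol and fatty acid synthesis, immediate early and heat shock, mitochondrial encoded, reactive astrocyte, disease-associated oligodendrocyte, glutamatergic and GABAergic synapse, and ambient RNA of neurons and of glia. Comparisons, lists, the rule for named genes and the alternatives were fixed before the data were examined, except those said to be chosen after seeing the data. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, and again with the correlation estimated from the residuals, adjusted over the lists and contrasts of a class. Of 273 such tests 82 gave a call and 20 of these were also called with the estimated correlation. List scores, shares of nuclei and the levels of single genes over all nuclei were compared with exact two-sided permutation tests of the mean. A ratio of UMIs with 1 to 3 in a group has a 95% exact (Clopper-Pearson) interval, and a group at 0 was given a floor of 3 counts, both for counting error only.

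The fits were tested on simulated data, negative binomial counts with the depths and dispersions of these libraries in which 100 genes were changed 2-fold and 100 genes 4-fold. In microglia the P301S comparison recovered 61 and 97 of them and the MK-2206 comparison in P301S 80 and 98, with 0 called in the wrong direction. Alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, each replicate left out and, in microglia, doublets kept, a strict filter (at least 500 genes and at most 1% mitochondrial), Leiden resolution 2.0, genes of free RNA left out, and only the 2 groups compared. An alternative chosen after seeing the data added to the fit whether the number in a library's label lies above the median of the P301S libraries. All mTrem2_control libraries lie above it. Versions were Python 3.11.15, anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, umap-learn 0.5.12, matplotlib 3.10.9 and R 4.3.3.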

Results

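Single-nucleus RNA sequencing measured the RNA of nuclei from mouse hippocampus in 19 libraries that the labels place in 5 groups. All groups but mTrem2_control (4 libraries), labelled with the mouse gene, are labelled with the R47H form of human TREM2, a receptor of microglia. R47H_control (3 libraries) has neither the P301S mutation nor the drug, and R47H_control_MK2206 (4 libraries) was given MK-2206, an inhibitor of the kinase AKT. R47H_P301S (4 libraries) carries P301S, a mutation of the microtubule protein tau that is used to model tau disease in mice, and R47H_P301S_MK2206 (4 libraries) carries it and was given the drug. The labels give each library a number of its own but do not state that the libraries of a group came from separate animals. Each p-value of a gene, share or score thus measures a difference against the spread between these libraries. A list p-value from camera instead sets the genes of a list against the other genes tested. With the preset correlation of 0.01 it rests on that assumed value. Total UMIs (unique molecular identifiers, counted molecules) were 40823324, 42056136, 42728100 and 39208462 in mTrem2_control and 43600475, 45622641 and 49291978 in R47H_control. They were 35942608, 52214368, 47858571 and 48961912 in R47H_control_MK2206 and 42012478, 42842195, 40632724 and 47773745 in R47H_P301S. They were 41432667, 45439639, 45914647 and 45871737 in R47H_P301S_MK2206. Each library kept 8161 to 11719 nuclei with a median of 2262 to 3731 UMIs per nucleus.

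Marker genes named 28 of 39 clusters. The 197074 nuclei kept held 55221 of excitatory neurons other than granule cells (28.0%), 35781 of oligodendrocytes (18.2%), 28774 of dentate granule neurons (14.6%), 20888 of astrocytes (10.6%), 12690 of inhibitory neurons (6.44%) and 9533 of microglia (4.84%). These class names mean "like" the cell type, since they rest on RNA markers alone. Smaller classes were oligodendrocyte precursors (5932 nuclei), fibroblasts (3554), choroid and ependymal cells (3020) and Cajal-Retzius cells (671). The 11 clusters left unnamed held 21010 nuclei (10.7%). At Leiden resolution 1.0 no cluster met the naming rule for endothelial, mural, other immune or immature neuronal cells; at Leiden resolution 2.0 a cluster of 359 nuclei met it for endothelial and 1 of 365 for mural cells. Microglia gave 353 to 740 nuclei and 290986 to 783861 UMIs per library, which limits the genes that can be tested in them to 7634. Values below are group means ± SD over the libraries of a group, in CPM (counts per 1e+06 UMIs of the class), unless stated otherwise.

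Genes named by the labels were read first. Trem2 was measured at 191 ± 10.7 CPM in microglia of mTrem2_control and 139 ± 25.8 CPM in those of R47H_control. That difference had an exact permutation p of 0.0286, the smallest these group sizes allow, and 0.186 after adjustment over 52 tests. The other R47H groups had Trem2 means of 145 ± 19.1 CPM (R47H_control_MK2206), 159 ± 23.6 CPM (R47H_P301S) and 144 ± 22.3 CPM (R47H_P301S_MK2206). Mapt, the mouse tau gene, was at 425 ± 41.2 CPM over all nuclei of R47H_control and 461 ± 37.5 CPM over those of R47H_P301S (exact permutation p = 0.257). Human TREM2 and human tau were not analysed here. Prnp, the prion protein gene, had 0.426 ± 0.132 CPM in R47H_control and 0.860 ± 0.0868 CPM in R47H_P301S, with an exact permutation p of 0.0286 and 0.186 after adjustment. These values rest on few counts, 14 to 23 UMIs per R47H_control library and 31 to 34 per R47H_P301S library. A separate annotated entry named Prn held more, with 18 to 46 and 55 to 80 UMIs. The level of Prnp alone may thus not give that of the gene. Xist, transcribed from the inactive X chromosome of females, was at 1131 to 1700 CPM in every library, and 4 Y-linked genes together reached at most 1.13 CPM. In each of the 27 pairs of libraries within a group, counts differed by more than resampling of 1 library would give (chi-square per gene 5.86 to 37.7).

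To find what differed with P301S on the R47H background, R47H_P301S was compared with R47H_control within each cell class. In microglia, genes of the interferon response and of the disease-associated state were higher with P301S, and fewer genes were lower. H2-D1 (ENSMUSG00000073411, chromosome 17, 35262730 to 35267499), a class I histocompatibility gene, rose 3.96-fold from 45.1 ± 4.30 to 181 ± 39.3 CPM (log2 fold change 1.98, SE 0.21, adjusted p = 1.85e-06). Cd9, a tetraspanin, rose 2.42-fold from 151 ± 30.1 to 362 ± 76.6 CPM (adjusted p = 0.000862). Siglech, a lectin of resting microglia, fell from 1238 ± 90.3 to 885 ± 84.5 CPM (log2 fold change -0.52, SE 0.11, adjusted p = 0.0128). In all, 80 genes rose and 28 fell among the 7634 tested in microglia.

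**Figure D1:**
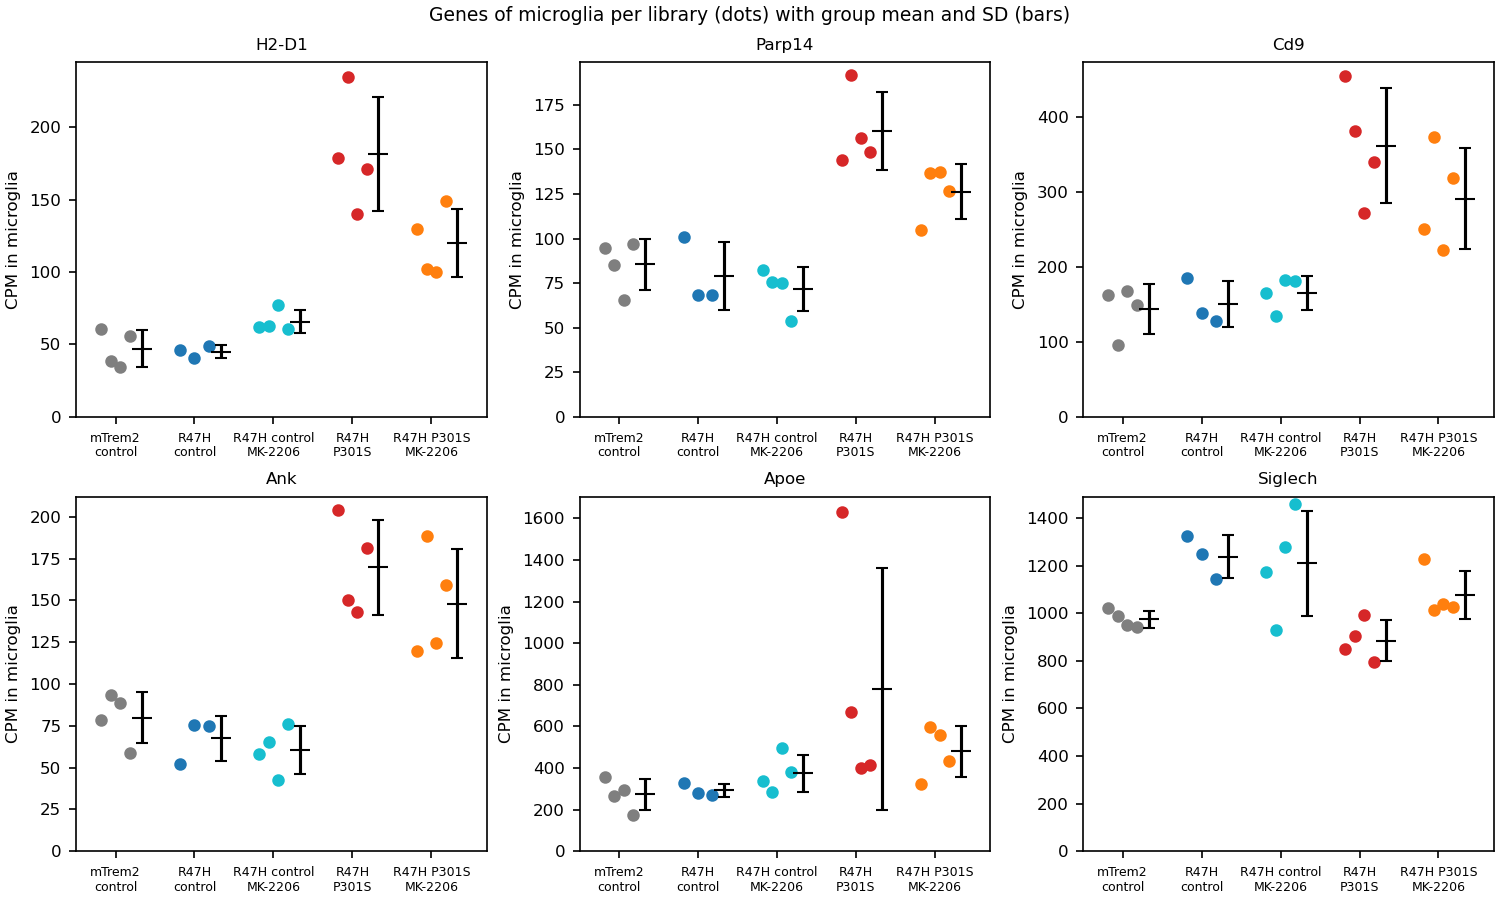
CPM of 6 genes in summed microglia, 1 dot per library, with group mean and SD as bars, for the 5 groups. H2-D1, Parp14, Cd9 and Ank are highest in R47H_P301S; Apoe has a group SD of 581 CPM there, and Siglech is lower there than in R47H_control.

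Of 31 interferon response genes tested in microglia, 30 had a log2 fold change above 0, with a median of 0.94. Over all genes tested 16 of them rose, and 24 rose when adjusted over the list alone. The list was called at an adjusted p of 7.64e-33, and at 0.000376 with an estimated correlation. Sp100 (log2 fold change 1.76), Ddx60 (1.41) and Parp14 (1.02) were among those that rose. Of 22 genes of the disease-associated state, 20 were above 0 (median 0.94), 10 rose over all genes and 16 rose adjusted over the list alone (list adjusted p = 3.61e-16; adjusted p = 0.0288 with an estimated correlation). They include Ank, a phosphate transporter, from 67.5 ± 13.4 to 170 ± 28.3 CPM, Colec12, a scavenger receptor, from 18.0 ± 16.5 to 137 ± 74.8 CPM, and Myo1e, a membrane-bound myosin, from 53.8 ± 12.6 to 177 ± 71.3 CPM. Apoe, the lipid carrier, rose from 293 ± 31.9 to 780 ± 581 CPM (adjusted p = 0.023); that call was lost without R47H_control replicate 1 (adjusted p = 0.0632), 2 (0.108) or 3 (0.105) or R47H_P301S replicate 1 (0.142).

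Of 12 antigen presentation genes, 10 were above 0 in microglia (median 0.51), with 4 higher over all genes and 5 adjusted over the list alone. Its list call (adjusted p = 3.62e-06) was lost at an adjusted p of 0.115 with an estimated correlation. H2-K1 rose from 60.1 ± 16.5 to 157 ± 45.3 CPM and B2m from 77.9 ± 13.1 to 147 ± 18.7 CPM. Cd74, the invariant chain of class II molecules, had 2 UMIs in R47H_control and 166 in R47H_P301S, a ratio of 43.8 (95% exact interval 11.9 to 365, counting error only; edgeR adjusted p = 0.0011). Ccl4, a chemokine of the NF-kB and cytokine list, had 3 and 109 UMIs, a ratio of 19.2 (interval 6.39 to 94.4; adjusted p = 0.00189). Of that list's 14 genes 12 were above 0 (median 0.21), with 1 higher over all genes and 3 adjusted over the list alone. It was called at an adjusted p of 0.0232, but at 0.164 with an estimated correlation and at 0.127 without R47H_P301S replicate 1. Of 30 homeostatic genes, 3 were above 0 (median -0.29), with 2 lower over all genes (Siglech and Bank1) and 7 adjusted over the list alone. The call of that list (adjusted p = 5.7e-08) was lost at an adjusted p of 0.271 with an estimated correlation.

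Other genes that rose in microglia were Rftn1 (log2 fold change 1.45), March3 (1.46), Myo5a (1.43) and Hif1a (1.11), the last a regulator of the response to low oxygen. Genes that fell were Hlf (-1.45), Adcy8 (-1.34), Myo1d (-1.02), Myo18b (-0.90), Kcnk12 (-0.81), Glis3 (-0.73) and the scavenger receptor Stab1 (-0.71). Akt1 (-0.12), Akt2 (0.46), Trem2 (0.17) and Mapt (-0.44) were not called. The lists of PI3K-AKT pathway components (median -0.05, adjusted p = 0.848), FOXO targets (-0.07, 0.717), glycolysis (0.15, 0.25), sterol and fatty acid synthesis (0.17, 0.426) and immediate early and heat shock genes (-0.08, 0.717) were not called. Neuronal transcripts that leak between nuclei, read with the neuronal ambient RNA list, had a median of -0.41 in the same comparison (adjusted p = 1.04e-06; adjusted p = 0.271 with an estimated correlation). All 10 mitochondrial genes were below 0 (median -0.37, adjusted p = 0.0157; adjusted p = 0.597 with an estimated correlation), and that call was lost without R47H_control replicate 3 (0.135) or R47H_P301S replicate 1 (0.103) or 2 (0.135). The count of 108 microglial genes was 58 without R47H_control replicate 1, 42 without replicate 2, 57 and 59 without R47H_P301S replicates 1 and 2, 185 without replicate 3, and 256 with no filter on low counts. Of the 27 named genes called, 12 were called with every library left out in turn.

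**Figure D2:**
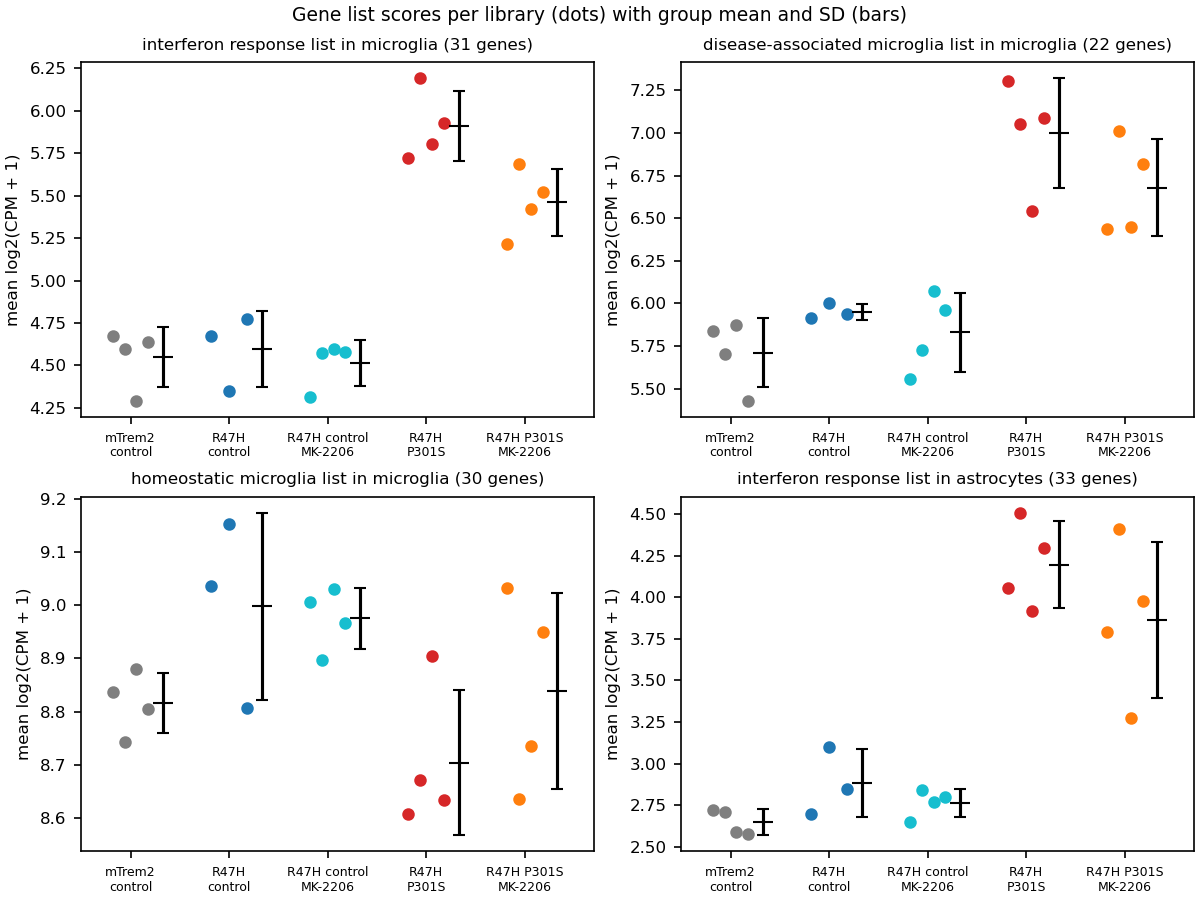
Mean log2(CPM + 1) of the genes of a list, 1 dot per library, with group mean and SD as bars, for 3 lists in microglia and 1 in astrocytes. The interferon score of microglia is 5.72 to 6.19 in the 4 R47H_P301S libraries and 5.21 to 5.69 in the 4 R47H_P301S_MK2206 libraries.

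In astrocytes, 12 of 12113 genes rose with P301S and 0 fell in the edgeR test (645 had an unadjusted p under 0.05; DESeq2 called 16 in all). Gfap (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912), the intermediate filament of reactive astrocytes, rose 2.64-fold from 138 ± 8.88 to 368 ± 104 CPM (log2 fold change 1.40, SE 0.22, adjusted p = 0.00359). C4b (ENSMUSG00000073418, chromosome 17, 34728380 to 34743882), a complement component, rose 2.70-fold from 58.7 ± 3.42 to 161 ± 37.0 CPM (1.43, SE 0.23, adjusted p = 0.0038). Of 33 interferon response genes 32 were above 0 (median 1.41), and 7 rose over all genes against 28 adjusted over the list alone (list adjusted p = 9.38e-47; adjusted p = 0.00211 with an estimated correlation). Ddx60, an interferon-induced helicase, rose from 6.25 ± 2.09 to 41.0 ± 13.6 CPM, and Oasl2 and Nlrc5 rose by 3.59 and 2.22 on the log2 scale. Gbp2 had 2 UMIs in R47H_control and 43 in R47H_P301S, a ratio of 13.9 (95% exact interval 3.61 to 118). Of 26 reactive astrocyte genes 22 were above 0 (median 0.60), with 4 higher over all genes and 11 adjusted over the list alone (list adjusted p = 7.27e-19; adjusted p = 0.00571 with an estimated correlation). The genes of sterol and fatty acid synthesis had a median of -0.21 (adjusted p = 1.85e-05; adjusted p = 0.288 with an estimated correlation), and all 11 mitochondrial genes were below 0 (median -0.43, adjusted p = 7.59e-05; adjusted p = 0.288 with an estimated correlation). The count of 12 was 7 without R47H_control replicate 1 or 2, 6 without replicate 3, 6 without R47H_P301S replicate 2, 24 without replicate 3, and 96 with no filter on low counts. It was 7 when the mTrem2_control group, which stands apart in its cell makeup, was left out of the fit, an alternative chosen after seeing the data.

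In oligodendrocytes, 3 of 11801 genes were called higher with P301S. C4b rose from 23.8 ± 6.84 to 141.8 ± 71.7 CPM (log2 fold change 2.60, SE 0.41, adjusted p = 0.00504), H2-D1 from 7.36 ± 3.16 to 33.5 ± 6.67 CPM (2.11, SE 0.33, adjusted p = 0.00504), and the noncoding gene Gm43049 is described with the neurons. All 16 interferon response genes tested were above 0 (median 0.55), with 0 called over all genes and 8 higher adjusted over the list alone (list adjusted p = 1.09e-15; adjusted p = 0.0124 with an estimated correlation). The list of disease-associated oligodendrocytes had a median of 0.26 over 18 genes, with 2 higher over all genes and 5 adjusted over the list alone (adjusted p = 0.000532; adjusted p = 0.0386 with an estimated correlation). Antigen presentation had a median of 0.91 over 5 genes, with 1 higher over all genes and 3 adjusted over the list alone (adjusted p = 0.0006; adjusted p = 0.0227 with an estimated correlation). Of the 3 calls, 0 were left without R47H_control replicate 1 and 1 without replicate 3, and C4b and H2-D1 had adjusted p-values of 0.0697 and 0.0731 without replicate 1. With no filter on low counts 61 genes were called.

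In neurons without the drug, the calls with P301S came from 1 part of chromosome 3 (build mm10). Gm43049 (ENSMUSG00000105777, 140692038 to 140760704), a predicted gene, was at 77.1 ± 8.88 CPM over all nuclei of R47H_P301S and 83.2 ± 4.06 CPM in R47H_P301S_MK2206, against 0.183 ± 0.104 CPM in R47H_control and 0.184 CPM in mTrem2_control. Its log2 fold change was 8.92 (SE 0.25, adjusted p = 2.61e-16) in other excitatory neurons and 7.52 (SE 0.27, adjusted p = 3.91e-17) in inhibitory neurons. In granule neurons it had 1633 UMIs against 2, a ratio of 757 (95% exact interval 209 to 6260), and in oligodendrocytes 90 against 1, a ratio of 62.1 (10.9 to 2480). Its level in oligodendrocytes of R47H_P301S, 5.46 to 12.9 CPM, lies far below the 78.2 to 109.5 CPM in other excitatory neurons, and RNA leaked from neurons was not separated from RNA of the oligodendrocytes. Gm32754 (140904998 to 140917459) was at least 220-fold higher and 4930590L14Rik (140951876 to 140953247) at least 39.9-fold higher in other excitatory neurons, taking 3 counts over the R47H_control group, where both had 0 UMIs, as the floor. Unc5c (141465216 to 141834924), a netrin receptor gene, fell in inhibitory neurons from 1267 ± 133 to 843 ± 81.3 CPM (log2 fold change -0.59, SE 0.10, adjusted p = 0.00749). These genes make up all calls in granule neurons (2 of 14583), other excitatory neurons (3 of 17593) and inhibitory neurons (3 of 13487). They were chosen for their values, since the rule for named genes leaves out predicted genes. Among lists, interferon response genes of other excitatory neurons had a median of 0.39 over 32 genes, with 29 above 0, 0 called over all genes and 6 higher adjusted over the list alone (adjusted p = 2.15e-14; adjusted p = 0.0255 with an estimated correlation). Without R47H_P301S replicate 3, 7 genes were called in other excitatory neurons, and DESeq2 called 6 there. With no filter on low counts the counts were 11, 5 and 23. P301S against control was also compared among the libraries given the drug, an alternative chosen after seeing the data. It called 11, 8 and 7 genes in granule, other excitatory and inhibitory neurons. Of these, 2, 3 and 3 were called without the drug too, and the others are not described here.

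**Figure D3:**
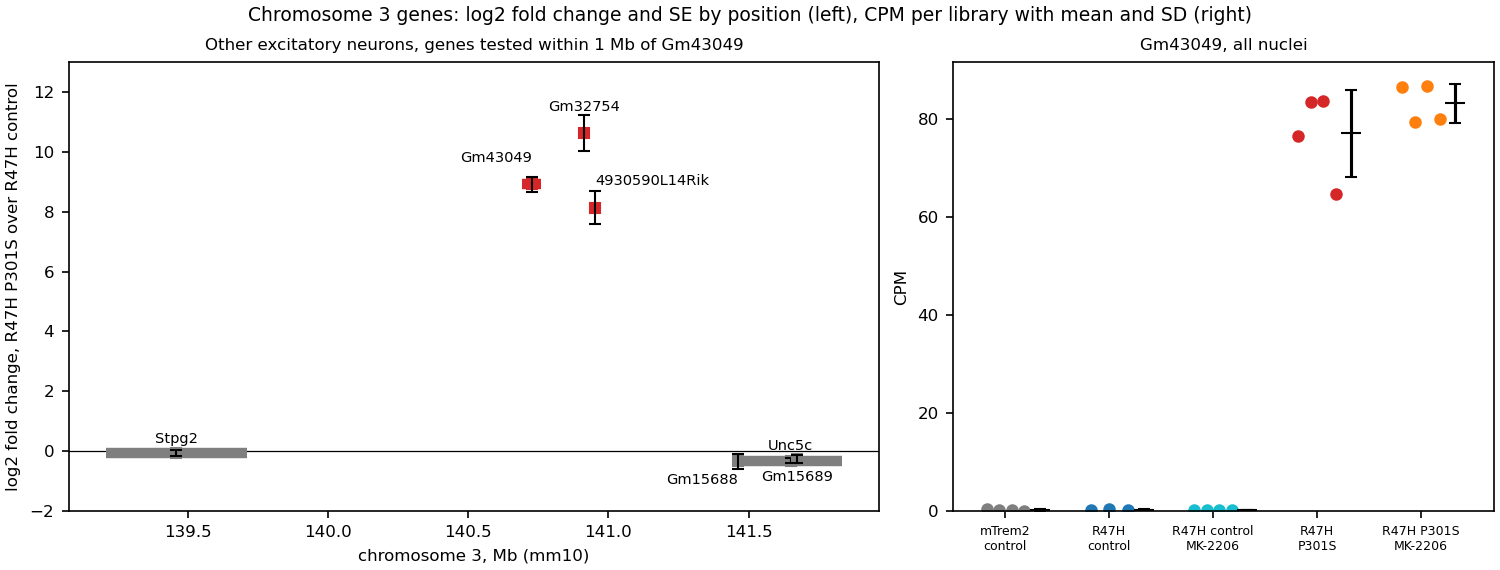
Left, log2 fold change of R47H_P301S over R47H_control with SE in other excitatory neurons against position on chromosome 3 (Mb, mm10) for the genes tested within 1 Mb of Gm43049, red where called; Gm32754 and 4930590L14Rik had 0 UMIs in R47H_control, so their plotted values depend on the prior count of the fit. Right, CPM of Gm43049 over all nuclei, 1 dot per library with group mean and SD: the 3 genes summed reach at least 72.5 CPM in each of the 8 P301S libraries and at most 0.345 CPM in the 11 others.

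To ask whether the AKT inhibitor changed the response to P301S, R47H_P301S_MK2206 was compared with R47H_P301S. In microglia 1 of 7634 genes passed the edgeR test (462 had an unadjusted p under 0.05; DESeq2 called 1). Sla (chromosome 15, 66780819 to 66831829), an adaptor protein gene, rose from 120 ± 8.03 to 205 ± 36.7 CPM (log2 fold change 0.76, SE 0.13, adjusted p = 0.0149). As a group, interferon response genes were lower with the drug: 29 of the 31 had a log2 fold change below 0, with a median of -0.36. The list was called at an adjusted p of 4.55e-11, and at 0.0288 with an estimated correlation; 0 of its genes passed over all genes tested and 5 were lower adjusted over the list alone. The interferon score, the mean log2(CPM + 1) of these genes, was 5.91 ± 0.21 in R47H_P301S and 5.46 ± 0.20 in R47H_P301S_MK2206, against 4.60 ± 0.22 in R47H_control. The difference between the P301S groups, -0.45, had an exact permutation p of 0.0286, the smallest possible, and 0.131 after adjustment over 32 tests. Members with the smallest p-values, not called singly, were H2-D1 of the antigen list at 120 ± 23.6 CPM (log2 fold change -0.61, SE 0.15, adjusted p = 0.299), Eif2ak2 at 71.4 ± 14.2 against 112.1 ± 28.4 CPM, and Lgals3bp at 12.5 ± 5.85 against 25.8 ± 2.96 CPM.

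The list of disease-associated microglia had a median of -0.30 with the drug in P301S microglia, with 4 of 22 genes above 0, 0 called over all genes and 3 lower adjusted over the list alone. It was called at an adjusted p of 0.000662, but at 0.362 with an estimated correlation, 0.0808 without R47H_P301S replicate 1 and 0.0784 without R47H_P301S_MK2206 replicate 1. Lyz2 of this list was at 17.3 ± 7.39 against 41.0 ± 22.3 CPM and was not called. Homeostatic genes had a median of 0.15, with 23 of 30 above 0 (adjusted p = 0.00167; adjusted p = 0.509 with an estimated correlation); that call was lost without R47H_P301S replicate 1 (0.0526) or R47H_P301S_MK2206 replicate 1 (0.211) or 4 (0.0552). Siglech was at 1078 ± 101.8 CPM with the drug (log2 fold change 0.29, not called). All 10 mitochondrial genes were above 0 (median 0.77), with 9 higher adjusted over the list alone and 0 over all genes (list adjusted p = 9.83e-08; adjusted p = 0.271 with an estimated correlation). Moving with them, neuronal ambient RNA genes had a median of 0.22 (adjusted p = 0.000653; adjusted p = 0.422 with an estimated correlation) and glial ambient RNA genes one of 0.45 (adjusted p = 0.0151; adjusted p = 0.271 with an estimated correlation). The glial ambient call was lost without R47H_P301S replicate 3 (0.06) or R47H_P301S_MK2206 replicate 2 (0.178). Of the 8 P301S libraries, those with the lower numbers in their labels are 3 of R47H_P301S and 1 of R47H_P301S_MK2206. With high or low label number as a covariate, an alternative chosen after seeing the data, the interferon list had a median of -0.42 (adjusted p = 8.44e-12) and the mitochondrial list one of 0.42 (adjusted p = 0.00337), and the neuronal and glial ambient lists were not called (adjusted p = 0.279 and 0.261). The PI3K-AKT (median -0.03, adjusted p = 0.38) and FOXO target lists (0.14, 0.0886), which hold parts and downstream genes of the inhibited pathway, were not called. The call of Sla was lost without R47H_P301S replicate 1 (0.0512) or 3 (0.0734) and without R47H_P301S_MK2206 replicate 1 (0.0869), 2 (0.0616) or 4 (0.0563). It was also lost under the strict filter (adjusted p = 0.0514) and with the 2 groups fitted alone (0.338), and 47 genes were called with no filter on low counts.

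In astrocytes of P301S libraries, 0 of 12113 genes passed the edgeR test with the drug (703 had an unadjusted p under 0.05; DESeq2 called 5). All 33 interferon response genes had a log2 fold change below 0 (median -0.28; adjusted p = 4.26e-08, but adjusted p = 0.167 with an estimated correlation), and 2 were lower adjusted over the list alone. Genes of sterol and fatty acid synthesis had a median of 0.37, with 28 of 30 above 0 and 6 higher adjusted over the list alone (adjusted p = 6.13e-11; adjusted p = 0.133 with an estimated correlation). All 11 mitochondrial genes were above 0 beside them (median 0.79; adjusted p = 8.47e-14; adjusted p = 0.0586 with an estimated correlation). The edgeR count was also 0 in oligodendrocytes, granule neurons, other excitatory neurons and inhibitory neurons (628, 783, 1116 and 989 genes had an unadjusted p under 0.05; DESeq2 called 1, 0, 2 and 0). In oligodendrocytes sterol and fatty acid synthesis genes had a median of 0.16, with 23 of 30 above 0 and 1 higher adjusted over the list alone (adjusted p = 0.00148; adjusted p = 0.0303 with an estimated correlation). In other excitatory neurons interferon response genes had a median of -0.20 (adjusted p = 1.57e-05; adjusted p = 0.357 with an estimated correlation). Without 1 library the astrocyte count was 8 (R47H_P301S replicate 4) or 9 (R47H_P301S_MK2206 replicate 1), and with no filter on low counts the counts were 85 in astrocytes, 62 in oligodendrocytes and 73 in inhibitory neurons.

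To see the effect of the drug without P301S, R47H_control_MK2206 was compared with R47H_control. In microglia 0 genes passed the edgeR test (352 had an unadjusted p under 0.05; DESeq2 called 0; smallest adjusted p 0.969), and no list was called. The interferon list had a median of 0.06 (adjusted p = 0.82), PI3K-AKT components 0.04 (0.586) and FOXO targets 0.15 (0.165). In astrocytes 29 of 30 sterol and fatty acid synthesis genes were above 0 (median 0.33, adjusted p = 5.54e-08, and adjusted p = 0.231 with an estimated correlation). The mitochondrial list was called in granule neurons, but without R47H_control replicate 1 that call was lost and its direction turned (adjusted p = 0.999). Capn11, a calpain protease gene (chromosome 17, 45630204 to 45659325), rose in granule neurons from 2.07 ± 0.677 to 8.95 ± 1.24 CPM (log2 fold change 2.10, SE 0.32, adjusted p = 0.0138) and in inhibitory neurons from 2.30 ± 0.5683 to 11.8 ± 1.06 CPM (2.33, SE 0.37, adjusted p = 0.0124). Mid1, an X-linked ubiquitin ligase gene, fell in inhibitory neurons from 50.4 ± 12.3 to 19.1 ± 6.19 CPM (-1.40, SE 0.25, adjusted p = 0.0363). Over all nuclei Mid1 was at 50.7 to 79.3 CPM in R47H_P301S_MK2206 and 36.6 to 80.5 CPM in R47H_P301S, ranges that overlap. Capn11 was at 1.20 to 2.37 CPM in granule and 1.20 to 2.53 CPM in inhibitory neurons of R47H_P301S_MK2206, against 0.934 to 4.49 and 1.19 to 7.18 CPM in R47H_P301S, so the treated P301S libraries do not have the higher level; the interaction was not tested in neurons. The edgeR count was 0 in astrocytes, oligodendrocytes and other excitatory neurons (640, 806 and 1133 genes had an unadjusted p under 0.05; DESeq2 called 0, 0 and 4). The granule neuron call was lost without R47H_control replicate 1 or 3, R47H_control_MK2206 replicate 1 or 2, or the mTrem2_control group. The inhibitory calls numbered 0 without R47H_control replicate 1 or 3 or R47H_control_MK2206 replicate 4, and 1 without R47H_control_MK2206 replicate 1 or 3, without the mTrem2_control group or with DESeq2.

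The interaction of drug and mutation in microglia asks whether the drug effect differed with P301S. In the edgeR test 0 genes passed (423 had an unadjusted p under 0.05; DESeq2 called 0; smallest adjusted p 0.358), and 42 did with no filter on low counts. Interferon response genes had a median interaction of -0.23 on the log2 scale, with 8 of 31 above 0 and 2 lower adjusted over the list alone. That list was called at an adjusted p of 1.82e-05, and lost at 0.164 with an estimated correlation.

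Fold changes across genes were compared to see whether the drug effect ran opposite to the P301S effect in microglia. Across 7634 genes, which are not independent replicates, Pearson's r was -0.508 and Spearman's rho -0.465. Both contrasts use the R47H_P301S libraries, and 20 simulated groups with no drug effect gave r of -0.445 to -0.388 by this sharing alone. With the R47H_P301S libraries split so that the contrasts share none, 6 splits gave a mean r of -0.125 (-0.236 to -0.0159), and the 11 to 115 genes called higher with P301S in a split had medians of -0.66 to -0.125 on the log2 scale with the drug (mean of the 6 medians -0.37). The 1 to 68 genes called lower with P301S had medians of -0.28 to 0.14, below 0 in 1 of the 6 splits and above 0 in 5. Among the libraries given the drug, P301S against control called 23 microglial genes, 20 higher and 3 lower, and 17 of them were called without the drug too, an alternative chosen after seeing the data. Cd9 (log2 fold change 0.82), Ank (1.29) and H2-D1 (0.85) were among the genes that rose there, and interferon response genes had a median of 0.69 (p = 0.00017 with an estimated correlation). The drug effects with and without P301S had r of -0.0186 and rho of -0.0031 across the same genes, with the same sign in 49.6% of them.

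To ask what R47H changed without P301S or drug, R47H_control was compared with mTrem2_control. The mTrem2_control libraries differ from R47H_control in makeup: clusters left unnamed held 27.4 ± 7.08% of their nuclei against 6.02 ± 1.36%, and granule neurons 7.46 ± 3.57% against 17.9 ± 1.09% (exact permutation p = 0.0571 for each). At Leiden resolution 2.0 the difference in unnamed nuclei was -14.1 points (exact p = 0.0286, adjusted p = 0.471) in place of -21.4 points (adjusted p = 0.359). In microglia 10 genes rose and 4 fell of 7634. Of those that rose, 7 are mitochondrial, such as mt-Co2 from 83.6 ± 30.3 to 284 ± 82.3 CPM (log2 fold change 1.81, SE 0.27, adjusted p = 0.00168) and mt-Co3 from 135.5 ± 29.7 to 400 ± 66.4 CPM. Bcl2, which blocks cell death, rose from 35.2 ± 12.9 to 93.1 ± 14.1 CPM (1.39, SE 0.30, adjusted p = 0.0432). Ccnd3, a G1 cyclin, fell from 1750 ± 253 to 826 ± 227 CPM (-1.05, SE 0.23, adjusted p = 0.0467), Tfeb, a transcription factor of lysosomal genes, from 147 ± 11.9 to 83.5 ± 5.67 CPM (-0.78, SE 0.16, adjusted p = 0.0348), and Nrg1, a growth factor, from 185 ± 56.8 to 69.8 ± 10.2 CPM (-1.37, SE 0.24, adjusted p = 0.00598). Nrg1 is also a leading gene of unnamed cluster 6, which held 16.5 ± 5.49% of nuclei in mTrem2_control and 1.35 ± 1.21% in R47H_control. Sfi1 also fell (-1.61). The mitochondrial list had a median of 1.69 (adjusted p = 3.42e-18; adjusted p = 0.0498 with an estimated correlation), with 7 genes higher over all genes and 9 adjusted over the list alone. Homeostatic genes had a median of 0.15, with 26 of 30 above 0 (adjusted p = 0.000541; adjusted p = 0.469 with an estimated correlation and 0.0695 without R47H_control replicate 2; 0.107 with high or low label number as a covariate). The lists of interferon response (median -0.02, adjusted p = 0.717), disease-associated microglia (0.27, 0.0809) and PI3K-AKT components (-0.03, 0.456) were not called. The count of 14 was 4 without mTrem2_control replicate 2 or 3, 5, 4 and 9 without R47H_control replicates 1, 2 and 3, 26 with doublets kept, 4 under the strict filter, 23 with the 2 groups alone and 95 with no filter on low counts. With high or low label number as a covariate the calls of Bcl2, Ccnd3 and Tfeb were lost (adjusted p = 0.135, 0.225 and 0.104).

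In astrocytes 81 genes rose and 53 fell of 12113 between R47H_control and mTrem2_control. Mitochondrial genes were higher there too, with a median of 1.36, 9 genes higher over all genes and 10 adjusted over the list alone (adjusted p = 9.18e-17; adjusted p = 0.0357 with an estimated correlation). Genes of the immediate early and heat shock list had a median of -0.54 over 20 genes, with 3 lower over all genes and 10 adjusted over the list alone (adjusted p = 0.000186; adjusted p = 0.0357 with an estimated correlation), and Fos (-2.08) and Nr4a1 (-2.35) fell. Pde10a, a phosphodiesterase gene, fell from 1189 ± 778 to 118 ± 48.3 CPM (log2 fold change -3.35, SE 0.48, adjusted p = 0.000316). Other genes that fell were Irs2 (-1.79), Gabbr2 (-1.60), Btg2 (-1.39), Pde7b (-1.32) and Map3k19 (-1.21), and Mamdc2 (2.41), H2-D1 (2.23) and Mob3b (1.47) rose. For the genes that fell, Pde10a among them, RNA leaked from cells more frequent in mTrem2_control was not separated from RNA of astrocytes. In oligodendrocytes 41 genes rose and 24 fell of 11801, with mt-Nd3 (1.67), mt-Atp6 (1.38) and mt-Cytb (1.36) among those that rose and Nrg1 (-1.17), Ahsa2 (-0.96), Tjap1 (-0.90) and Dscaml1 (-0.85) among those that fell. Sterol and fatty acid synthesis genes had a median of 0.28 in oligodendrocytes (adjusted p = 0.000251; adjusted p = 0.0184 with an estimated correlation). The astrocyte count was 56 without mTrem2_control replicate 2, 45 and 29 without R47H_control replicates 1 and 2, 404 with no filter on low counts, and 75 with high or low label number as a covariate, where Fos, Nr4a1, Irs2, Map3k19 and Mamdc2 were not called. The oligodendrocyte count was 6, 8, 26 and 16 without mTrem2_control replicates 1, 2, 3 and 4, 15, 8 and 19 without R47H_control replicates 1, 2 and 3, 122 with DESeq2, 320 with no filter and 13 with that covariate, where Nrg1, Ahsa2, Tjap1 and Dscaml1 were not called.

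In neurons the same comparison called 84 genes in granule neurons (57 higher, 27 lower), 1591 in other excitatory neurons (778 higher, 813 lower) and 408 in inhibitory neurons (194 higher, 214 lower). Mid1 rose in each, by 1.73 (SE 0.36, adjusted p = 0.0275), 1.93 (SE 0.37, adjusted p = 0.00269) and 1.87 (SE 0.26, adjusted p = 0.000146) on the log2 scale. Bdnf, a neurotrophin, rose in granule neurons from 52.3 ± 9.96 to 89.4 ± 11.2 CPM (0.79, SE 0.14, adjusted p = 0.0144), as did Gphn (0.30), an anchor of receptors at inhibitory synapses, while Dpp10 (-1.01) and Xbp1 (-0.85) fell. In other excitatory neurons Rictor (0.30), a part of an AKT-activating complex, and the transcription factor gene Foxo1 (0.67) rose. The PI3K-AKT list itself was not called there (median -0.01, 3 genes higher, adjusted p = 0.862). Cdkn1a (-1.81), Fosb (-1.08), Nptx2 (-0.97) and Nr4a1 (-0.63) fell, and the immediate early and heat shock list had a median of -0.43 over 30 genes, with 5 lower over all genes and 13 adjusted over the list alone (adjusted p = 1.81e-05; adjusted p = 0.442 with an estimated correlation). In inhibitory neurons that list had a median of -0.55, with 4 lower over all genes and 6 adjusted over the list alone (adjusted p = 5.78e-05; adjusted p = 0.394 with an estimated correlation), and Arc (-1.98) and Npas4 (-1.31) fell. Mitochondrial genes had medians of 1.74 in granule (adjusted p = 3.27e-10; adjusted p = 0.382 with an estimated correlation), 1.59 in other excitatory (adjusted p = 2.03e-09; adjusted p = 0.357 with an estimated correlation) and 1.69 in inhibitory neurons (adjusted p = 4.69e-16; adjusted p = 0.188 with an estimated correlation). The list of glutamatergic and GABAergic synapse genes went both ways in other excitatory neurons, with 11 of 67 higher and 12 lower (adjusted p = 0.841).

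Within the excitatory class the mTrem2_control libraries also had another mix of clusters, since cluster 8 held 27.7% of the class in them against 12.2% in R47H_control and cluster 9 held 13.4% against 22.3%. With the 8 of 13 clusters whose shares differed by no more than 1.5 times, an alternative chosen after seeing the data, 277 genes were called in place of 1591. Foxp2, Ipcef1 and Sema3a, which fell over the whole class (-1.33, -1.27 and -1.24), had log2 fold changes of 0.08, 0.02 and 0.05 over those clusters. Of the 33 named genes, 10 kept direction and call there, among them Mid1 (2.10) and mt-Co2 (1.67), 20 kept direction and lost the call, and these 3 turned. Without 1 library the other excitatory count was 942 (mTrem2_control replicate 2), 939 or 880 (R47H_control replicates 2 and 3), and the inhibitory count 196 (mTrem2_control replicate 2), 219, 214 or 267 (R47H_control replicates 1, 2 and 3). The granule neuron count was 27, 0, 14 and 154 without mTrem2_control replicates 1, 2, 3 and 4, 28, 4 and 6 without R47H_control replicates 1, 2 and 3, 288 with DESeq2 and 251 with no filter, and the inhibitory count with no filter was 712. With high or low label number as a covariate the granule neuron count was 55, and the calls of Mid1 and Gphn in granule neurons, Foxo1 in other excitatory neurons and Arc in inhibitory neurons were lost (adjusted p = 0.0963, 0.0943, 0.0668 and 0.0934).

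The share of each class among the nuclei of a library was compared to see whether cell types were lost or gained. Of 44 exact two-sided permutation tests, 0 had an unadjusted p under 0.05, the smallest p the group sizes allow was 0.0286, and the smallest adjusted p was 0.359. Microglia made up 6.27 ± 1.28% of nuclei in R47H_P301S and 4.60 ± 1.004% in R47H_control (exact p = 0.143). They made up 5.14 ± 0.983% in R47H_P301S_MK2206, 4.21 ± 0.378% in R47H_control_MK2206 and 4.12 ± 0.0886% in mTrem2_control. Granule neurons made up 14.1 ± 1.70% in R47H_P301S against 17.9 ± 1.09% in R47H_control (exact p = 0.0571) and 16.9 ± 1.86% in R47H_P301S_MK2206. Oligodendrocytes made up 13.7 ± 1.58% in mTrem2_control against 18.6 ± 2.66% in R47H_control, and other excitatory neurons 23.5 ± 2.96% against 30.3 ± 0.859%.

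**Figure D4:**
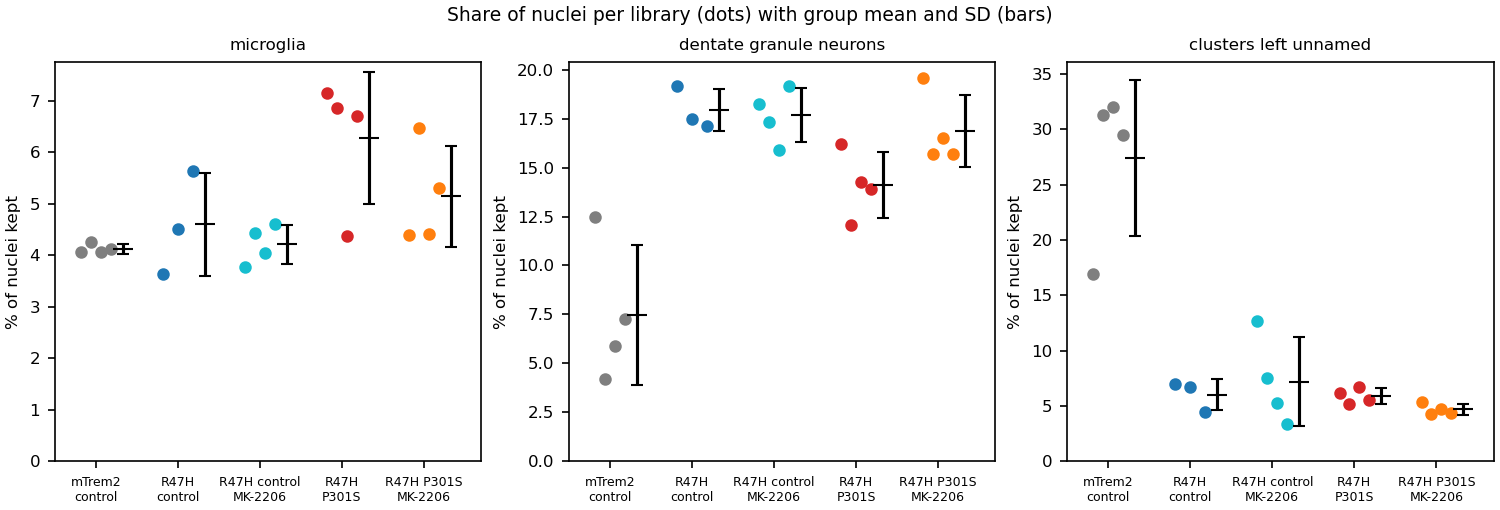
Percent of the nuclei kept that fell into microglia, dentate granule neurons and clusters left unnamed, 1 dot per library with group mean and SD as bars. The mTrem2_control libraries have the lowest mean of granule neurons (7.46%) and the highest mean of unnamed nuclei (27.4%).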

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

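The tests of makeup of the excitatory class, of free RNA in mTrem2_control and of nuclear preparation were written before their results were seen, and all other tests in this part were chosen after the result they concern was seen.

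In microglia with P301S, interferon response genes were lower with MK-2206 (median log2 fold change -0.36). Dilution of microglial RNA by RNA of other cells would lower homeostatic genes alike, but their median was 0.147 (quartiles 0.032 to 0.274, against -0.575 to -0.233 for the interferon genes), which argues against it. A single library as the source is also argued against, since the interferon median was at most -0.251 with any 1 of the 8 libraries left out. Mitochondrial genes were higher with the drug too, and with the mitochondrial score as a covariate the drug difference of the interferon score was -0.519 (SE 0.152) against -0.451 (SE 0.132) without it, which argues against nuclear preparation as read from them. An effect of MK-2206 itself and a difference in handling between the groups that the labels do not record both stay open and untested; with high or low label number as a covariate the interferon median was -0.415.

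Many genes differed between R47H_control and mTrem2_control, most of them in neurons. Another makeup of the excitatory class may account for part of the calls in that class. With clusters of even share 277 genes were called, against 1088 with UMIs over all clusters thinned to the same depth (34.7 to 45.8% kept). With all UMIs 1591 were called. The thinning kept all clusters, so the effect of fewer nuclei in the even clusters was not tested. In inhibitory neurons 408 genes were called. Each of the 3 clusters there had a share within 1.04 times between the groups, which argues against another mix of these clusters. Another mix of cells within a cluster, and RNA leaked into inhibitory neurons, were not tested. RNA of cells that are frequent in the mTrem2_control libraries may also reach glia. Leading genes were read for 3 unnamed clusters with at least 3 times the share there. Their median log2 fold change was -0.319 in astrocytes (21 genes, 3 called lower and 2 higher). It was -0.457 in oligodendrocytes (20 genes, 2 lower, 0 higher) and -1.03 in microglia (8 genes, 1 lower, 0 higher). These clusters were chosen for their share in mTrem2_control, so any wider excess in those libraries may enter their leading genes. The medians thus cannot tell leaked RNA from such an excess. Mitochondrial level and depth also differed between these groups. Mitochondrial genes, read above for nuclear preparation, had a microglial score of 7.06 in R47H_control against 5.46 in mTrem2_control. Mean total UMIs were 46170000 against 41200000 (exact permutation p = 0.0286, adjusted p = 0.343). Neither was tested as a cause. An effect of R47H itself stays open and untested beside all of these, because makeup, mitochondrial level, depth and genotype differ between the same libraries.

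Genes of 1 part of chromosome 3 were far higher in neurons with P301S. A mislabelled library is argued against, since all 19 libraries lay on the side of their label. Without the drug, the 3 other genes called in neurons, Gm32754 and 4930590L14Rik (higher) and Unc5c (lower), lay within 1 Mb of Gm43049. This place was chosen because they lie there, so their number is no test of it. The 3 genes that rose span 261.2 kb. Among genes of the matrices with a known position, the nearest one at lower coordinates ends 879.3 kb before them. A candidate explanation that stays open is a change of the DNA at this place in the P301S libraries, such as a transgene inserted there, which the counts alone do not show.

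Other splits of the same libraries were run for each count of called genes. A share of 1 of 35, the real split alone, is the smallest possible. It was not adjusted for the 25 counts tested, so it does not exclude chance. For P301S, the splits could not exclude chance for the microglial count of 108, which 2 of 35 splits reached: grouping R47H_P301S replicate 3 with the 3 R47H_control libraries gave 157 genes, so replicate 3 is set apart from the other P301S libraries. The next split gave 39. Libraries given the drug, none of them among these, argue against chance: P301S against control called 23 genes there, 17 of them among the 108, and 76 of the 80 genes called higher without the drug were above 0 there. For P301S no other split reached the 12 astrocyte genes (1 of 35 splits, highest other 8). The real count was 6 or 7 without any 1 of the R47H_control replicates. Among the libraries given the drug, P301S against control called 21 astrocyte genes, 5 of them among the 12. All 12 were above 0 there. The 3 oligodendrocyte genes were reached by 2 of 35 splits (highest other 32). Among the libraries given the drug, P301S against control called 7 oligodendrocyte genes, 1 of them among the 3. All 3 were above 0 there. No other split reached the 2, 3 and 3 genes of granule, other excitatory and inhibitory neurons (1 of 35 each, highest others 1, 2 and 2). For MK-2206 in P301S chance could not be excluded for the 1 microglial gene (8 of 35, highest other 22). The other classes had 0 genes, which each of 35 splits reaches, so their splits say nothing of chance (highest others 8 in astrocytes, 5 in oligodendrocytes, 11 in granule, 56 in other excitatory and 15 in inhibitory neurons). In these 5 classes the highest other split is 1 and the same: it sets R47H_P301S replicates 1, 2 and 3 and R47H_P301S_MK2206 replicate 1 against the rest, which parts the 8 libraries by the order of the numbers in their labels. This split differs from the real one only in that R47H_P301S replicate 4 and R47H_P301S_MK2206 replicate 1 change sides. It thus cannot tell a structure that follows these numbers from these libraries being unlike the rest of their groups. The order was noticed after the splits were seen, and the labels do not give the meaning of the numbers. In microglia the highest other split is another one. For MK-2206 without P301S no other split reached the 2 inhibitory genes (1 of 35, highest other 1). That count was 0 without R47H_control replicate 1 or 3 or R47H_control_MK2206 replicate 4. The 1 granule neuron gene was reached by 3 of 35 splits (highest other 3). The splits say nothing of chance for the 0 genes of microglia, astrocytes, oligodendrocytes and other excitatory neurons (highest others 1, 1, 2 and 0). For R47H no other split reached the real count in any class (1 of 35 each). The real counts were 14, 134, 65, 84, 1591 and 408 in microglia, astrocytes, oligodendrocytes, granule, other excitatory and inhibitory neurons. The highest others were 4, 56, 1, 50, 726 and 180. With a replicate left out the microglial count fell as low as 4, the astrocyte count to 29 and the granule neuron count to 0, which the highest other splits reach. The 0 genes of the interaction are reached by each of 100 drawn splits, so these say nothing of chance (highest other 11).

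The interaction of drug and mutation in microglia differed from 0 for 4 lists by its own test with the preset correlation. Their median log2 interactions were -0.229 (interferon response), 0.824 (mitochondrial encoded), 0.461 (neuronal ambient RNA) and 0.188 (homeostatic), and none was called with an estimated correlation (adjusted p of 0.164, 0.362, 0.362 and 0.597). The homeostatic call (adjusted p = 0.0165) was lost without R47H_control replicate 1 (0.0888) or 2 (0.347), R47H_control_MK2206 replicate 2 (0.0745), R47H_P301S replicate 1 (0.0994) or 4 (0.0659), or R47H_P301S_MK2206 replicate 1 (0.211) or 4 (0.108).

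A single library lay far from the other 3 of its group in 18 of 268 sets of 4 values, where chance gives about 13.4. R47H_P301S_MK2206 replicate 1 had 41432667 UMIs in all (others 45439639 to 45914647), a Cajal-Retzius share of 0.611% (others 0.409 to 0.426%), Mapt at 407.6 CPM over all nuclei (others 523.2 to 543.2) and Siglech at 1230 CPM in microglia (others 1016 to 1040). Replicate 2 of that group had Colec12 at 96.5 CPM in microglia (others 72.2 to 74.8). R47H_P301S replicate 3 had a microglia share of 4.38% (others 6.70 to 7.15%). Replicate 1 of that group had an inhibitory neuron share of 5.69% (others 6.54 to 6.65%) and Capn11 at 5.80 CPM over all nuclei (others 1.31 to 2.01). Among mTrem2_control libraries, replicate 1 had 27.9% of other excitatory neurons (others 21.7 to 22.7%) and 16.9% of unnamed nuclei (others 29.5 to 32.0%). In the same group replicate 2 had a mitochondrial score of 4.76 in microglia (others 5.69 to 5.73) and Gbp2 at 1.72 CPM in astrocytes (others 0.613 to 0.765), and replicate 4 had Myo5a at 52.8 CPM in microglia (others 27.4 to 31.4). Among R47H_control_MK2206 libraries, replicate 1 had an interferon score of 4.31 in microglia (others 4.57 to 4.60) and replicate 2 a reactive astrocyte score of 4.75 (others 4.701 to 4.706) and Adcy8 at 113.3 CPM in microglia (others 62.8 to 65.3). Replicate 3 of that group had H2-D1 at 77.3 CPM in microglia (others 60.6 to 62.9), and replicate 4 had Trem2 at 2.26 CPM over all nuclei (others 1.52 to 1.65).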

How the results depend on the processing

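The alternatives of this part that were chosen after seeing the data are the fit without the mTrem2_control group, the even clusters, the UMIs thinned to them, and high or low label number (above or below the median of the P301S libraries) as a covariate. RLE size factors, Leiden resolution 2.0 and genes of free RNA left out kept each count of genes they were run for within 1.5 times. With no filter on low counts the called genes numbered 256, 47, 21, 95 and 42 in microglia (P301S, MK-2206 in P301S, MK-2206 without P301S, R47H and interaction). In the order of the first 4 of these contrasts they numbered 96, 85, 37 and 404 in astrocytes, 61, 62, 124 and 320 in oligodendrocytes, 11, 2, 21 and 251 in granule neurons and 23, 73, 54 and 712 in inhibitory neurons. In other excitatory neurons they numbered 5 (P301S) and 1 (MK-2206 without P301S). DESeq2 called 5 genes in astrocytes and 1 in oligodendrocytes (MK-2206 in P301S), 122 in oligodendrocytes and 288 in granule neurons (R47H), 3 in granule and 1 in inhibitory neurons (MK-2206 without P301S), and 6, 2 and 4 in other excitatory neurons (P301S, MK-2206 in P301S and without). In microglia, the strict filter gave 0 (MK-2206 in P301S) and 4 (R47H), the 2 groups alone 0, 1 and 23 (MK-2206 in P301S, without P301S, and R47H), and doublets kept 26 (R47H) and 1 (interaction). Without the mTrem2_control group 7 genes were called in astrocytes (P301S), 0 in granule and 1 in inhibitory neurons (MK-2206 without P301S). The even clusters gave 277 genes (R47H, other excitatory neurons), with Foxp2 at 0.077, Ipcef1 at 0.022 and Sema3a at 0.052 in place of negative values. The estimated correlation left 20 of 82 list calls. With high or low label number as a covariate 75 genes were called in astrocytes, 13 in oligodendrocytes and 55 in granule neurons (R47H) and 1 in inhibitory neurons (MK-2206 in P301S). It kept 68 list calls and 128 named genes and lost 14 and 28, with none turned. The cause of these moves was not tested, except that the thinned UMIs (1088 genes) show that fewer UMIs alone do not give 277. Thinning kept the nuclei of all clusters, so the smaller number of nuclei in the even clusters stays untested.

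With each replicate left out, counts in microglia ranged from 42 to 185 (P301S), 0 to 3 (MK-2206 in P301S), 0 to 0 (without P301S), 4 to 16 (R47H) and 0 to 0 (interaction). In astrocytes they ranged from 6 to 24, 0 to 9, 0 to 0 and 29 to 1.5e+02 (rounded), in oligodendrocytes from 0 to 4, 0 to 2, 0 to 1 and 6 to 26, in granule neurons from 2 to 2, 0 to 1, 0 to 2 and 0 to 154, in other excitatory neurons from 3 to 7, 0 to 1, 0 to 0 and 880 to 1504, and in inhibitory neurons from 2 to 4, 0 to 1, 0 to 2 and 196 to 451. List calls ranged from 71 to 85, and the correlations of fold changes from -0.602 to -0.426 and from -0.0547 to 0.0128. Shares past the threshold ranged from 0 to 0. The smallest p that such small groups allow leaves almost no room for a call, so that 0 says nothing of stability. The mitochondrial list of granule neurons (MK-2206 without P301S) turned direction without R47H_control replicate 1 (adjusted p = 0.999, with a range of 9.5e-09 to 0.999 over the replicates left out). Over all called lists, 1440 results with a replicate left out kept direction and call and 117 lost the call; for named genes 750 kept it and 338 lost it. RLE size factors kept 81 list calls and 155 named genes and lost 1 of each. A sex covariate was not run, since all libraries are female. No paired analysis was possible because replicates carry no pairing in the labels. The depth of microglia (290986 to 783861 UMIs per library) limits which genes could be tested there.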

Other observations

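The count of genes next to Trem2 and the reading of astrocyte genes in microglia were chosen after their values were seen.

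Some unnamed clusters held a larger share of nuclei in mTrem2_control than in R47H_control. Cluster 6, led by Rgs6, Nrg1 and Cdh4, held 16.5 ± 5.49% of nuclei in mTrem2_control and 1.35 ± 1.21% in R47H_control. Cluster 23, led by Ankfn1, Ano1 and Pld5, held 4.50 ± 2.99% against 0.693 ± 0.706%, and cluster 25, with the GABA receptor gene Gabra6 among its leading genes, 0.856 ± 0.887% against 0.0893 ± 0.104%. Cluster 12, led by the heat shock gene Hspa1a and by Mdm2, held 4.12 ± 0.719% against 1.88 ± 0.338%.

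Slc1a3, a glutamate transporter gene of astrocytes, was at 3130 CPM in microglia of R47H_control replicate 1 and 2270 CPM in those of R47H_P301S_MK2206 replicate 2, against 220 to 441 CPM in the 17 other libraries. Slc1a2, another astrocyte transporter gene, was at 55.0 and 94.0 CPM in these libraries and 41.0 to 101 CPM in the others.

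Among the 14 genes called with R47H in microglia, 2 lie within 1 Mb of Trem2 on chromosome 17, Ccnd3 (47505051 to 47599691) and Tfeb (47737030 to 47792419), where 7 of 7633 tested genes lie. The window was chosen after these genes were seen, so this number is no test of it. A change of the DNA at Trem2 that reaches its neighbours may be one reason, as a hypothesis that stays open. The call of each gene was lost with 6 of the 7 libraries left out in turn, and with high or low label number as a covariate (adjusted p = 0.225 and 0.104). In the 12 libraries of the other R47H groups Ccnd3 was at 513.6 to 1798 CPM in microglia, with 11 below the lowest mTrem2_control library (1388 to 1957 CPM), and Tfeb at 92.8 to 144 CPM, with 11 below the lowest (139.7 to 164.5 CPM). In astrocytes 1 of 134 called genes, Ccnd3, lies there, in other excitatory neurons 1 of 1591, and in oligodendrocytes, granule and inhibitory neurons 0. Capn11, which rose in neurons with MK-2206 without P301S, ends 2.69 Mb before Trem2.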
